A study of Rattus norvegicus with 6 samples.

How the data were processed

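RNA from H9c2 cells, a myoblast line established from embryonic rat heart, was compared on 6 two-colour expression arrays. Each array held RNA from cells transfected with a plasmid carrying ApoO and RNA from cells transfected with the plasmid pTT alone. ApoO encodes apolipoprotein O, a protein of the mitochondrial inner membrane. Per the labels' protocols, plasmids were introduced by electroporation together with a neomycin resistance vector, transfectants were selected with the drug, total RNA was extracted with Trizol, and the RNA was labelled directly. Per the labels, channel 1 was Cy5 and channel 2 Cy3, and the dyes were swapped. ApoO RNA was in Cy5 on replicates 1, 3 and 5 and in Cy3 on replicates 2, 4 and 6. All 6 arrays are called biological replicates in the labels, and every sample is given as passage 6. The culture text in the labels describes embryonic stem cells on feeder cells, which is not the H9c2 line, and no culture condition was taken from it.

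The authors deposited 1 table of log ratios, treated here as log2 by assumption, with 1 value per probe and array. It is the only measurement used here. The scanner, feature extraction, background correction, normalization and filters are not given in the sources used here. The column medians lay between -0.0362 and 0.00264, so each array appears to have been centred before deposit. The base of the logarithm is not given either. Base 2 was assumed, because the highest value of 6.00 would be beyond the range of a common scanner in base 10. A natural logarithm was not excluded, so each fold stated is conditional on base 2. Which transfectant is in the numerator is also not given, and neither is whether the swapped arrays were turned before deposit. The titles of all 6 arrays name pTT against pTT-ApoO in that order with a dye swap, whichever the orientation. They do not say how the ratio was formed. Why cells of the table are empty is not given in the sources used here. Intensities were not used here, so signal over background is unknown, no probe could be judged dim or saturated, and the number of arrays limits the precision.

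Each ratio was split into a part with the same sign in both dye orientations and a part that changed sign with the orientation. These are called the shared component (the mean of the means of the 2 orientations) and the opposed component (their difference, ApoO in Cy5 minus ApoO in Cy3, divided by 2). If the authors had turned the swapped arrays before deposit, the shared component is the difference between the transfectants and the opposed component is the dye effect. If the table was left as channel over channel, the roles are exchanged. A rule fixed before the data were examined said that ratios would be turned only if arrays of opposite orientation correlated below 0. Their mean correlation was 0.236, so the ratios were kept as deposited, both components are reported, and no direction is given to either. A positive or negative ratio below is the sign in the table, and all signs turn if the ratio was formed the other way.

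Both components were fitted per probe with limma 3.58.1 (lmFit and eBayes, R 4.3.3) as an intercept and an orientation term, with 4 residual degrees of freedom. Probes with at least 2 values in each orientation were tested. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 23031 probes tested. Adjusted p-values of probes are from this limma fit, except where another setting is named. The fit was tested on simulated data with the real empty cells and the real opposed component for 23031 probes, 200 of them changed. Noise was drawn from a normal distribution with the variance of each probe as moderated by limma. Such noise matches the assumptions of the fit, so the rates may be favourable. For the shared component the fit recovered 22.0% of changes of 0.25, 94.0% of changes of 0.5 and 100% of changes of 1 or 2. Of its calls, 5.95% were false. The simulated arrays were independent and only 200 probes were changed. In the real data some arrays deviated together and 58.4% of probes were called, so these rates need not hold for the real fit. Whether the cultures behind the 6 arrays were independent is not stated beyond the word biological, so p-values measure only the spread between these arrays.

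Probes are named in the table by a code of 2 digits, a letter and 2 digits, with 72 leading digit pairs, 16 letters and 24 trailing digit pairs. None of the codes (0 of 27648) matched an identifier, symbol or accession in the rat gene table used here, which belongs to assembly GRCr8. No gene was therefore named, the probe of ApoO itself was not analysed here, and 26 gene lists fixed before the data were examined (559 genes, covering mitochondrial, lipid, stress, cell cycle, muscle and other cell type genes) were not tested. The rule for named genes was kept as far as codes allow. Among probes called with the same sign on all 6 arrays, the 2 with the highest and the 2 with the lowest shared component are named, in place of 12 genes each way. The leading digits, letter and trailing digits have the form of plate, row and column positions and are called plate, row and column codes, which is a reading of the codes and not a statement of the authors.

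Alternatives were a fit without the orientation term, median centring, scaling, quantile normalization, array weights, robust eBayes, probes complete on all arrays, removal of flat probes, averaging of consecutive arrays, other thresholds, the opposite sign and leaving out each array. Added after the data were seen were removal of plate, row and column medians and a block for consecutive arrays. Position was examined with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, using 1000 shuffles of the probes.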

Results

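The dataset comprised 6 two-colour arrays comparing pools of ApoO transfectants with pools of control (pTT) transfectants of H9c2 cardiomyoblasts, in order to find the transcripts whose abundance differs when ApoO is overexpressed. ApoO RNA was labelled with Cy5 on 3 arrays and with Cy3 on the other 3. The table listed 27648 probes. Values were present for 24147 probes (87.3%) on replicate 3, the most complete array, and for 21760 (78.7%) on replicate 4, the least complete. All 6 arrays had a value for 20575 probes, while 2642 probes were empty on every array. The standard deviation of the log ratios over probes ranged from 0.465 on replicate 1 to 0.597 on replicate 5. After filtering, 23031 probes were tested.

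The largest ratios had the same sign in both dye orientations, and ratios of moderate size often did not. Of the 82 probes with a mean ratio of at least 2 in size on the arrays with ApoO RNA in Cy5, 77 (93.9%) had the same sign on the others. All 55 probes chosen in this way on the arrays with ApoO RNA in Cy3 did so. At a size of at least 1, the sign was the same for 72.9% of 1205 probes chosen on the first orientation and for 75.3% of 1052 chosen on the second. Probe 36F01 had the highest shared component of all tested probes. Its mean ratio was 3.67 ± 0.349 (SD, n = 3) with ApoO RNA in Cy5 and 4.32 ± 0.478 (SD, n = 3) with ApoO RNA in Cy3. Its shared component was 3.99 with a standard error of 0.127 (limma adjusted p = 5.74e-07), a 15.9-fold difference between the transfectants if the table holds turned base 2 ratios. Among probes called with the same sign on all 6 arrays, probe 20C16 followed with a shared component of 3.22 ± 0.0785 (SE, 6 arrays, limma adjusted p = 4.92e-07), or 9.33-fold under the same reading. At the other end of that set, probe 09E02 had a shared component of -2.67 ± 0.0654 (SE, 6 arrays, limma adjusted p = 4.92e-07), or 6.36-fold. The lowest shared component of all tested probes was -3.02, at a probe outside that set. Probe 31E06 had -2.66 ± 0.0815 (SE, 6 arrays, limma adjusted p = 5.74e-07), or 6.30-fold. The sign was the same on 6 of 6 arrays for these 4 probes, as the rule that chose them required. For probe 31E06 the ratio also differed between the orientations, at -3.48 ± 0.235 (SD, n = 3) with ApoO RNA in Cy5 and -1.83 ± 0.243 (SD, n = 3) with ApoO RNA in Cy3. Its opposed component was -0.82 (limma adjusted p = 2.75e-04). Probe 20C16 differed as well, at 2.93 ± 0.153 and 3.51 ± 0.282 (SD, n = 3 each), with an opposed component of -0.29 (limma adjusted p = 0.0142). The opposed components of probes 36F01 (-0.33, limma adjusted p = 0.0567) and 09E02 (-0.10, limma adjusted p = 0.219) did not pass the threshold.

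**Figure D1:**
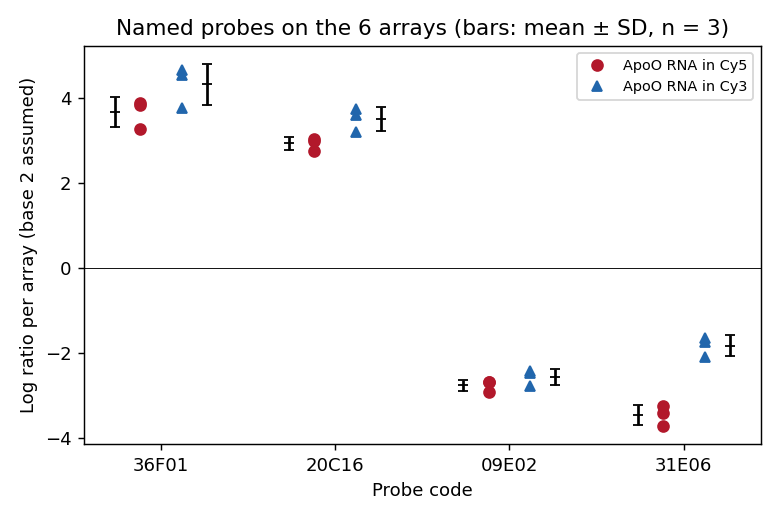
Log ratio (base 2 assumed) of 4 probes on each of the 6 arrays, as circles for ApoO RNA in Cy5 and triangles for ApoO RNA in Cy3, with the mean ± SD of each orientation (n = 3) beside them. Probes 36F01 and 20C16 lie above 0 on all 6 arrays and probes 09E02 and 31E06 below 0.

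The shared component passed the threshold at 13447 of the 23031 probes (58.4%), with a positive ratio at 6486 and a negative ratio at 6961. Most of these differences were small. Their median size was 0.34, the smallest called was 0.12, and 580 probes reached 1, which is 2-fold in base 2. Of those 580 probes, 286 were positive and 294 negative. A size of at least 2 was reached by 48 probes, 32 positive and 16 negative. A size of at least 3 was reached by 5 probes, 4 positive and 1 negative. Among all 13447 called probes, 74.9% had the same sign in both orientations and 50.1% had it on every array with a value. The opposed component was larger than the shared component at 25.1% of them, which are the probes whose sign differed between the orientations. Without the orientation term in the limma fit, the count fell to 5872 probes, while 578 with a size of at least 1 passed.

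**Figure D2:**
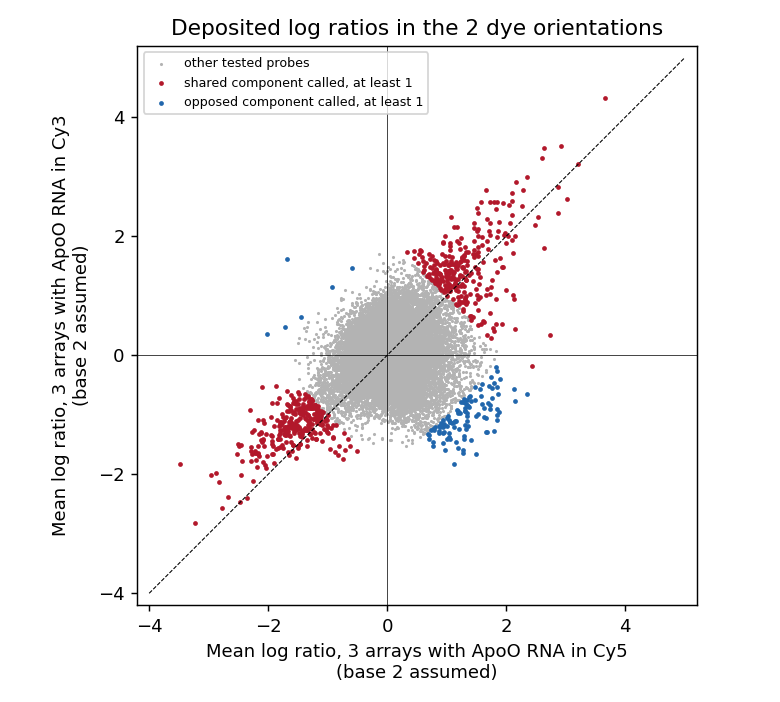
Mean log ratio (base 2 assumed) of the 3 arrays with ApoO RNA in Cy5 (x axis) against that of the 3 arrays with ApoO RNA in Cy3 (y axis) for 23031 probes, with the line of equality dashed. The 580 probes called for a shared component of at least 1 (red) extend along the line of equality, and most of the 115 called for an opposed component of at least 1 (blue) lie at lower right, where the ratio is positive with ApoO RNA in Cy5 and negative with ApoO RNA in Cy3.

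The opposed component, which a dye swap separates from the shared one, passed the threshold at 12217 probes (53.05%), 5660 positive and 6557 negative. It was smaller in range. It lay between -1.65 and 1.57, and none of the 12217 probes reached a size of 2, whereas the shared component ran from -3.02 to 3.99. A size of at least 1 was reached by 115 probes, of which 109 were positive and 6 negative. Both components passed at 6964 probes, where independent calls would give 7133. Neither passed at 4331 probes. The median standard deviation between arrays of one orientation was 0.153.

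Across probes, arrays of one dye orientation resembled each other closely, and arrays of opposite orientation did so only weakly. Pearson's r lay between 0.755 and 0.925 for the 6 pairs of arrays of one orientation. It lay between 0.104 and 0.427 for the 9 pairs of opposite orientation, with Spearman's rho between -0.0476 and 0.352. These are correlations over probes, which are not independent replicates. The mean ratio of the 3 arrays of one orientation correlated with that of the other at r = 0.262.

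The opposed component followed the probe code far more than the shared component did. Plate codes accounted for 14.7% of the variance of the opposed component over probes, row codes for 1.79% and column codes for 2.48%, each above the highest of 1000 shuffles (0.531%, 0.163% and 0.206%). For the shared component the plate codes accounted for 0.499%, just above the highest shuffle (0.490%). Row codes (0.0551%) and column codes (0.0870%) were within the range of the shuffles. Plate means of the opposed component ran from 0.32 at plate code 02 (343 probes) to -0.16 at plate code 71 (285 probes). Those of the shared component lay between -0.06 and 0.08 and rose weakly with plate number (Spearman's rho = 0.299). The plate means of arrays of opposite orientation were near mirror images, with r between -0.917 and -0.785 over the 72 plate codes for the 9 pairs. For the 6 pairs of one orientation r lay between 0.920 and 0.993.

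**Figure D3:**
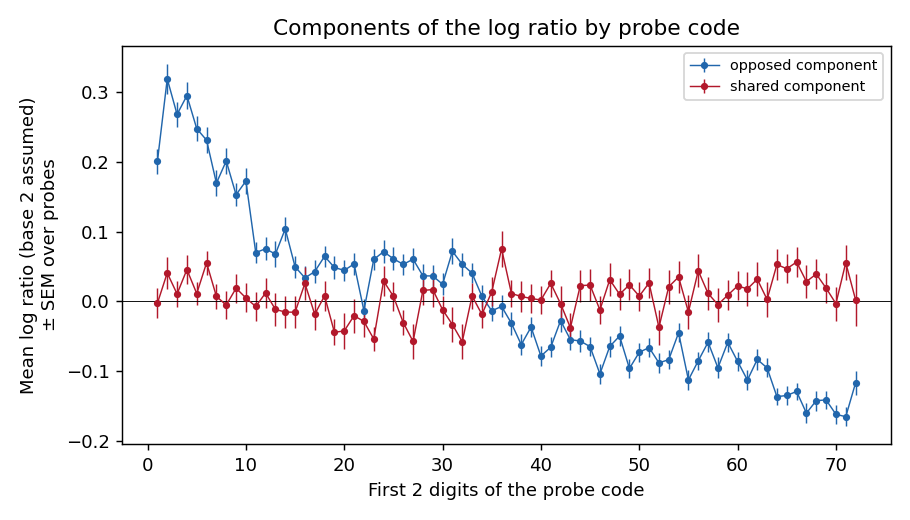
Mean of the opposed component (blue) and of the shared component (red), as log ratios in assumed base 2 with the standard error over probes (y axis), for each of the 72 values of the first 2 digits of the probe code (x axis). The opposed component declines from 0.32 at code 02 to -0.16 at code 71, while the shared component stays between -0.06 and 0.08.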

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

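The tests of printing position and of the pairing of arrays in this part were chosen only after the pattern had been seen, while the counts over sign patterns and splits and the tests of the array difference on plate codes and gain were fixed before their values were computed.

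The ratio differed between the dye orientations at 12217 probes by limma's orientation term. The shared component nevertheless reached larger sizes, at 48 called probes of at least 2 against 0 for the opposed one, which reached 1 at 115 probes. The question this leaves is whether the authors turned the swapped arrays. An unturned table whose shared component is a dye effect tied to printing position is argued against. Plate codes took 14.7% of the variance of the opposed component and 0.499% of the shared one. This comparison cannot show a dye effect that does not follow position, so such an effect is not argued against. An effect of position that is alike on all arrays falls in the opposed component only when the swapped arrays have been turned. In an unturned table with plates ordered by kind of gene, the opposed component could follow plates as a treatment difference, and its plate means did fall with plate number (Spearman's rho = -0.952). Plate means of the shared component rose weakly with plate number (Spearman's rho = 0.299). Gene order along the plates would not give effects of row and column that repeat over plates. Over all plates pooled, row codes took 1.79% and column codes 2.48% of the variance of the opposed component. Whether these effects repeat from plate to plate was not tested, so this reading stays open. It stays open too that arrays of one orientation were printed or hybridised apart from the others, because no array had the plate profile of the other orientation (highest r = -0.785). The reading of the shared component as the difference between transfectants is therefore not settled. A difference in biology between the transfectants stays open in both components.

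For the shared component, 1 of 31 sign patterns of the 6 arrays (the deposited signs) gave as many as 13447 called probes, and the highest of the others gave 39. At an unadjusted p under 0.05 the deposited signs had 14600 probes and the highest of the others, which turns all arrays but replicate 1, had 8999. The pattern that turns replicates 2, 4 and 6 was left out because it is the orientation term itself, which called 12217. With that structure set apart, no other pattern gave as many calls. A turned pattern moves a real shared signal into the residual spread, which lowers its adjusted calls. The 6 arrays are also not shown to be independent, since the deviations of replicates 1 and 2 correlated at r = 0.652. Chance is therefore not excluded as the source of the 13447 calls. For the opposed component, the 10 splits of the arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, called 12217 probes and the highest other called 0 with limma. At an unadjusted p under 0.05 the real split had 13615 probes and the others 24 to 1213.

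The arrays also differed within each orientation. Deviations from the orientation mean correlated at r = 0.652 over 20575 probes between replicates 1 and 2 and at 0.579 between replicates 5 and 6, against -0.638 between replicates 1 and 6. Effects that follow the plate codes are argued against as the main cause. Plate codes took 2.47% of the variance of the difference between replicates 1 and 2 and replicates 5 and 6. That share and those of row (0.192%) and column codes (0.627%) still lay above the highest of 1000 shuffles (0.528%, 0.179% and 0.240%). Effects of position on the slide that do not follow the codes were not tested. A difference in gain stays open, because the difference between these replicates correlated with the shared component at r = -0.463. Each array was also regressed on the mean of the others, over 511 complete probes called with a shared component of at least 1. The slopes were 0.944 and 0.875 on replicates 1 and 2, and 1.13 and 0.997 on replicates 5 and 6. On replicates 3 and 4 they were 0.996 and 1.03. Consecutive arrays may share RNA extracts or a working day. The 3 consecutive pairs had a summed correlation of 1.21, against 0.907 for the best of the 5 other pairings. Deviations cancel out over the 3 arrays of an orientation, so these correlations are tied. The high values of replicates 1 and 2 and of replicates 5 and 6 largely reflect a single contrast, which the sum counts more than once. With 6 pairings also too few for a test, the sum cannot decide, and replicates 3 and 4 gave -0.0250.

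The highest value of replicate 4 was 6.00, against at most 4.53 on the other arrays, at a probe that was empty on the other 5 arrays. It was 1 flag among 10 tests of the 6 arrays, and chance gives about 1 in 20.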

How the results depend on the processing

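The 4 named probes passed the threshold in all 68 values refitted under 17 settings, with sizes of at least 2.56. They were chosen for one sign on all arrays, so leaving out or averaging arrays could not turn it. They were also chosen as the most extreme called probes on these same arrays, so their size and their passing give no independent support. Their limma adjusted p was at most 7.35e-04, the highest without the orientation term. With the opposite sign of the ratio, which the table does not rule out, they become -3.99, -3.22, 2.67 and 2.66. The count of 580 probes with a shared component of at least 1 lay between 511 and 655 over 20 settings, of which the opposite sign and the 1.5-fold threshold could not change it. The count of 13447 was less stable. Without the orientation term it was 5872 (2867 positive, 3005 negative), all among the 13447. Requiring 1.5-fold in base 2 left 2357 (1410 positive, 947 negative), so that 59.8% were positive against 48.2% of all calls, and left 1135 of the 12217 opposed calls. At an adjusted p under 0.01 there were 9064, 4555 of them negative. Averaging consecutive arrays to 3 replicates gave 9693 calls and treating them as a random block 11202. Leaving out 1 array gave 10123 to 13799 shared and 9077 to 11850 opposed calls. Removing plate, row and column medians gave 13487 and 11290. Median centring gave 13375, scaling 13098, quantile normalization 13431 and array weights 16685. Those weights were 5.18 for replicate 3 and 2.17 for replicate 4, against 0.449 to 0.630 for the others, so few arrays dominate that fit. Other settings stayed within 1.5 times the count, and the causes were not tested. The orientations share no replicate number, so pairs were formed only from consecutive numbers, and a fixed block for them gave 13753 opposed calls among the 20575 complete probes. Alternatives for genes, for Apoo and for gene lists were not run, since no probe had a gene name. Signal over background is unknown, so its limits were not examined. The random and fixed blocks, the position correction and every setting given for opposed calls were chosen after seeing the data.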

Other observations

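The relation between plate codes and empty cells was examined after the plate pattern had been seen. Between 6.21% and 33.2% of the cells of a plate code were empty. Both this share and the mean opposed component ran along the plate number over the 72 plate codes (r = 0.609 and r = -0.926). The 2 measures correlated at r = -0.615 with each other, and at r = -0.173 after a linear trend with plate number was removed from both. Plates that follow a trend are not exchangeable, so no p-value is given, and the relation is not separable from the trend. For the shared component r was 0.0177, and -0.199 after removal of the trend. No explanation was tested.

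Empty cells were uneven between orientations. On all 3 arrays with ApoO RNA in Cy5 and on none of the others, 116 probes had a value, while 15 had the opposite pattern. Leaving out 1 array in turn, the first count ranged from 122 to 525 and the second from 15 to 64. The highest first count was without replicate 2 (525 and 15) and the highest second count without replicate 4 (122 and 64). Of the 2164 probes empty on exactly 1 array, 1118 were empty on replicate 4 and 149 to 282 on each of the others.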
